A study of Mus musculus with 12 samples.

How the data were processed

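The study sequenced RNA from lung and colon of mice labelled Rb1 wild type or Rb1 knockout. Per the labels' protocols, RNA was extracted from frozen tissue with TRIzol and chloroform, treated with DNase and checked on a Bioanalyzer before Illumina library preparation. The FPKM values were made by the authors, who aligned reads to the mouse genome build mm10 with TopHat and ran Cufflinks, Cuffmerge and Cuffdiff with RefSeq gene models, per the series' design text. Tool versions are not given in the sources used here. FPKM divides the reads of a gene by its length and by the sequencing depth, so the deposited values do not give the number of reads behind them.

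Samples were grouped by the tissue and genotype in their labels. Each column heading of the table was compared with the titles of the samples, with all other labels and with the series' text, ignoring case and punctuation (Python 3.11.15). Because no heading matched a title or any other label by name, the 12 value columns were not used in any calculation, and neither column order nor expression values were used to assign them. Only the headings and the gene column were analysed. Before the data were examined, a limma analysis of log2-transformed FPKM values within each tissue, a test of the difference between tissues, gene list tests and a set of alternatives had been planned. None of these was run.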

Results

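RNA was sequenced from the lung and colon of adult C57BL/6 mice, 96 hours after the last of a series of tamoxifen injections. The mice carried a Cre recombinase that tamoxifen activates, together with either wild-type or floxed alleles of Rb1, the gene for the retinoblastoma protein, a repressor of E2F-dependent transcription. The labels call the treated floxed animals Rb1 knockout, and the loss of Rb1 was not checked here. By the labels, the 12 samples form 4 groups of 3, namely wild-type and knockout colon and wild-type and knockout lung, and the extraction protocol states that both tissues came from each of 3 mice per genotype. The library numbers in the titles end in the same 6 digits in both tissues, with the same genotype at each digit, but the labels do not say whether that digit names the mouse. The design asks what acute loss of Rb1 changes in the transcriptome of each tissue, and it allows the response to be compared between the tissues.

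Expression was deposited as 1 table of FPKM values with 23793 gene rows and 12 value columns. The gene column holds 23537 distinct symbols, and 161 symbols stand on more than 1 row, which together make up 417 rows. Rb1 has 1 row. In the RefSeq annotation of GRCm38 the gene spans chromosome 14 from 73192858 to 73325951. The 40 pathway, cell type and technical lists, which were fixed before the data were examined, hold 632 distinct gene symbols. Of these symbols, 614 have a row under the same symbol. Every member has a row on 30 of the 40 lists, among them the 52 E2F targets of G1/S and DNA replication and the 76 nuclear genes of oxidative phosphorylation. The other 10 lists are covered in part. They include the G2/M and mitosis list with 43 of 45 members, where Foxm1 and Ccnf were not found. The list of Rb family, cyclin D, CDK and CDK inhibitor genes has 23 of 24, without Ccnd1. The erythroid list has 5 of 11, without Hbb-b1, Hbb-b2, Hbb-bs, Hba-a1, Hba-a2 and Ahsp. Only rows equal to a listed symbol were counted, so a gene not found may still stand in the table under another name. Since the values were not read, a row or its absence does not show whether a gene was expressed in lung or colon.

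The value columns are headed Sample1 to Sample12, with the 8th spelled Sampl8, whereas the samples are titled by library numbers such as BNa11 and BNa23. The number of column headings equal to a sample title was 0 of 12, and the number found anywhere in the labels of a sample was also 0 of 12. No column could be assigned to a tissue or genotype from its name. Column order was not used as evidence, since nothing in the labels says which order, if any, the columns follow. The accessions and the library numbers are 2 possible orders. Both place colon before lung and give the same genotype at 8 of the 12 positions. Sorted by accession, the wild-type libraries of each tissue precede the knockout libraries. Sorted by library number, colon libraries 13 and 14 and lung libraries 23 and 24 exchange places, which puts another genotype at the remaining 4 positions.

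With no column assigned by name, no comparison between knockout and wild type was made in colon or in lung, and the difference between the tissues was not tested. No expression value, fold change or test is given for Rb1, its E2F targets or any other gene. The depth of the libraries is unknown from FPKM values.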

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

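All rules for matching columns to samples were chosen after the column headings were seen. The number of columns matched was 0 when a heading had to equal a title and 0 when it was allowed anywhere in a sample's labels. It was 2 when the number in the heading had to equal the library number in a title, since the headings Sample11 and Sample12 share their numbers with 2 colon titles. The other 10 headings have no such partner, so this rule was not used. The other settings listed for the expression comparisons were not run, because those comparisons were not made. No paired analysis was possible because no column was assigned to a sample, and the labels do not say which libraries share a mouse.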
